A study of Mus musculus with 4 samples.

How the data were processed

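The data were 10x Single Cell 3' v2 UMI tables of 4 libraries, 1 per genotype, each from long-term hematopoietic stem cells sorted by flow cytometry from the bone marrow of C57BL/6 mice aged 8 to 11 weeks, per the labels' protocols. The genotypes were Mx (the MxCRE control), NPMc+, Flt3-ITD and NPMc+/Flt3-ITD. Reads had been counted per gene and barcode with STARsolo in STAR 2.7.0c on mm10, per the submitters' processing notes, and the deposited values were used as raw UMI count tables. The tables held whole numbers only, 11407 barcodes and 95244127 UMIs, with at least 101 UMIs per barcode. Of 26687 gene symbols, 25415 (95.2%) were found in GENCODE mouse release M21, which supplied coordinates and transcript lengths.

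The comparisons, gene lists, marker sets, filters, floors, folds, named-gene rule and 10 alternative settings were chosen before the data were examined. Another 4 settings (male cells, female cells, the top 1% of cells of each gene left out, and the T-lineage, erythroid and T or NK clusters left out) were chosen after the data had been seen. A barcode was kept with at least 1000 UMIs, at least 500 genes and at most 10.0% mitochondrial UMIs. This left 10608 cells: 2519 Mx, 2375 NPMc+, 2393 Flt3-ITD and 3321 NPMc+/Flt3-ITD. Of 799 barcodes left out, 786 had too few UMIs and 93 too many mitochondrial UMIs. Median UMIs per kept cell were 8094, 9466, 8661 and 7323, and median genes 3008, 3218, 3023 and 2952. Scrublet in scanpy called 32 cells doublets (0.302%). This may miss many doublets, and no loading density was at hand to check it, so its calls were used only as an alternative. Barcode sequences shared between libraries numbered 160.0 over all pairs, with both members kept for 52. A cell was called male with a UMI of Ddx3y, Eif2s3y, Kdm5d or Uty and none of Xist, and female with the reverse. This gave 1218 male and 583 female cells in Mx, 1155 and 495 in NPMc+, 987 and 773 in Flt3-ITD and 2425 and 179 in NPMc+/Flt3-ITD. Another 208, 283, 227 and 66 cells had both kinds of UMIs, and 510.0, 442, 406 and 651 had neither. Cells with both can be doublets or hold free RNA, so a sex call can be wrong and values for female cells carry that limit.

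UMIs were summed over the kept cells of each library and divided by the library total to give CPM. A gene entered a comparison with at least 20.0 CPM in either library and was counted as higher or lower from 2-fold. With 1 library per genotype no variance between animals could be estimated, so no p-values were computed and cells were not treated as replicates of a genotype. Ranges in the tests on flagged results came from resampling cells or genes of these libraries, and cover no variation between animals. Other intervals on ratios and shares are exact 95% intervals (Clopper-Pearson) and cover counting error only. Where a gene had 0 UMIs in either library, a floor of 3 counts gave the ratio as at least that value. TMM factors from edgeR, used as an alternative, were 1.046 for Mx, 0.948 for NPMc+, 0.946 for Flt3-ITD and 1.066 for NPMc+/Flt3-ITD.

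Named genes followed a fixed rule: the 12 highest and 12 lowest ratios of each comparison (6 and 6 for NPMc+/Flt3-ITD against NPMc+), the 4 members furthest from no difference in each list, and always Npm1, Flt3, Hoxa9, Meis1, Mki67, Cdkn1c, Cdk6, Cish, Socs2, Cd48, Cd34 and Procr. Some genes that the rule picks are not reported here. The ranking left out clone and prediction names, mitochondrial genes, immunoglobulin and T cell receptor segments, Xist, Tsix and Y-linked genes. T cell receptor segments were found by names that start with Tra, Trb, Trd or Trg. The gamma constant genes Tcrg-C1, Tcrg-C2 and Tcrg-C4 therefore stayed in. Gm5611, Gm14681, Gm15484, Hprt, the genes shown for the T-lineage cluster and the genes split by sex lay outside the rule and were chosen after their values were seen.

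There were 25 gene lists, 23 written out from general knowledge and 2 taken by name pattern (ribosomal proteins, mitochondrial genes). The pattern for ribosomal proteins also took 8 measured genes that encode none, kinase genes such as Rps6ka5 and a binding protein gene, so 86 of its 94 measured members are ribosomal protein genes. The lists were G1/S and S phase, G2/M phase, quiescence, LT-HSC identity, cell cycle entry and HSC activation, lymphoid and MPP priming, myeloid, megakaryocyte and platelet, erythroid, Hox and cofactors, STAT5 and cytokine feedback, TGF-beta, interferon-stimulated, antigen presentation, ribosome biogenesis and MYC, oxidative phosphorylation, glycolysis and hypoxia, immediate-early and dissociation stress, heat shock and unfolded protein, p53 targets, adhesion and niche, NF-kB and inflammation, and chromatin and leukemia-associated regulators. Of 855 names written, 846 matched a symbol and 738 were measured at a mean of 5 CPM or more over the 4 libraries. The unmatched names fell in the megakaryocyte list (35 of 37 matched), the erythroid list (25 of 27) and the oxidative phosphorylation list (54 of 59). A list's median log2 ratio was placed among the medians of 10000 random lists of the same size matched over 20.0 expression bins, and was called apart below percentile 2.5 or above 97.5. Its range came from 200.0 Poisson resamples of the counts. Random lists have independent members and real lists do not, so a percentile is a description and not a test.

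Cells were clustered on 2000 variable genes, 30.0 principal components and 15 neighbours with Leiden at resolution 0.5, without correction between libraries, since correction would also have removed the genotype. A cluster took a cell type name with at least 3 of that type's fixed markers among its 50.0 leading genes, and more than of any other type. For shares of cells with proliferation transcripts every cell was thinned to 3000 UMIs, leaving 2311, 2250, 2175 and 2991 cells. Correlations of ratios across genes used 50.0 Poisson resamples and a simulation of counting noise alone, in which no gene differed between libraries. That simulation does not stand for libraries with real but unrelated differences. Shared sequence was searched as exact matches of 50-base windows from the last 400.0 bases of 9464 genes, with no mismatch allowed. Only the match of Gm5611, Gm14681 and Gm15484 to Npm1 was searched with blastn.

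The procedure was tested on simulated data with counting noise only. In each of the 5 comparisons 50 of 50 genes simulated at 2.5-fold, 3-fold and 4-fold were called, 0 of 50 at 1.5-fold, and 0 of the 6238, 6185, 6214, 5841 and 5851 unchanged genes. Of 100.0 unchanged lists 0 were called, and of 100.0 lists of 40.0 members at 1.3-fold 100.0 were called. The simulation held no variation between animals, so it does not measure false calls from that source. Simulated folds were set only on genes with at least 40.0 CPM in the reference library. The calls therefore do not cover ratios that rest on few UMIs. Work was done in python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, leidenalg 0.10.2 and matplotlib 3.10.9, in R 4.3.3 with edgeR 4.0.16, and with blastn 2.17.0.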

Results

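The genes that name the genotypes were read first in the sorted long-term hematopoietic stem cells. Npm1, which encodes the nucleolar chaperone nucleophosmin (chromosome 11, 33152287 to 33163206, minus strand, mm10), stood at 1628 CPM (UMIs scaled to the library total) in the Mx control library, 1820 in NPMc+, 1724 in Flt3-ITD and 2180 in NPMc+/Flt3-ITD. Flt3, which encodes a receptor tyrosine kinase of multipotent progenitors (chromosome 5, 147330741 to 147400489, minus strand, mm10), stood at 29.9, 12.8, 31.8 and 70.9 CPM in the same order. The count tables hold no sequence, so neither mutant allele could be read from them. The Npm1-like processed pseudogene Gm5611 (chromosome 9, 17030045 to 17030896, mm10), chosen after its values were seen, separated the libraries along the NPMc+ label. It stood at 859 CPM in NPMc+ and 647 in NPMc+/Flt3-ITD, against 1.91 in Mx and 1.001 in Flt3-ITD, and was detected in 96.6% and 93.4% of cells against 1.59% and 0.919%. Gm14681 (399 and 297.5 CPM against 10.4 and 27.8) and Gm15484 (74.2 and 51.1 against 0.573 and 0.455), also chosen after their values were seen, followed the same division. Each library held cells of both sexes: cells with Y-linked UMIs and no Xist made up 67.6% of the sexed cells in Mx, 70.0% in NPMc+, 56.1% in Flt3-ITD and 93.1% in NPMc+/Flt3-ITD.

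Cells of the 4 libraries barely overlapped in a joint clustering. Clusters drawn at least 90% from a single library held 94.9% of Mx, 89.3% of NPMc+, 91.1% of Flt3-ITD and 97.7% of NPMc+/Flt3-ITD cells, so most clusters followed the library and could not be read as cell types. A megakaryocyte-like cluster, led by the immunoglobulin light chain gene Igkc, Hspa1a, Ms4a3 and the platelet chemokine gene Pf4, held 55.0% of NPMc+ cells (52.96 to 57.0%) and at most 0.813% of any other library. An HSC-like cluster with 5 stem cell markers among its leading genes, and Igkc too, held another 34.3% of NPMc+ cells. The border between them depended on the setting. The megakaryocyte-like cluster held 89.2% of NPMc+ cells at resolution 0.3, where no HSC-like cluster was found. At resolution 1.0, without cell cycle genes and with the stricter filter it held 39.5%, 37.6% and 36.7%, and the HSC-like cluster 36.3%, 51.8% and 53.01%. A cluster led by the T-lineage genes Trbc1, Tcf7, Tcrg-C2 and Bcl11b held 22.9% of NPMc+/Flt3-ITD cells (21.5 to 24.4%) and at most 0.168% of the others. The fixed rule left it unnamed, with 3 T or NK and 3 multipotent or lymphoid-primed progenitor markers, and it is called the T-lineage cluster below. Erythroid-like cells, led by Car1 and Klf1, made up 0.794%, 1.77%, 0.460% and 0.361% of Mx, NPMc+, Flt3-ITD and NPMc+/Flt3-ITD, and mature T or NK-like cells at most 0.334%. All of these cells had passed the flow-cytometric sort for long-term stem cells. Summed over fixed marker sets, the HSC markers stood at 1396, 1181, 761.7 and 588.2 CPM in that order, the multipotent or lymphoid-primed progenitor markers at 1022, 1423, 1888 and 4709, and the megakaryocyte markers at 733.9, 1799, 788.5 and 703.2. The B cell markers stood at 49.7, 1289, 76.5 and 199.1 CPM, the T or NK markers at 183.4, 447.6, 337.8 and 831 and the mast or basophil markers at 20.9, 116.1, 57.4 and 706.8. Erythroid markers stood at 2540, 3023, 2476 and 1127 CPM, granulocyte markers at 709.1, 697.2, 724.1 and 622.2 and monocyte, macrophage or dendritic markers at 1201, 997.1, 578 and 943.3. Endothelial markers stood at 146.2, 117.5, 129 and 107.8 CPM and stromal markers at 4.39, 3.23, 6.41 and 33.5 CPM.

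**Figure D1:**
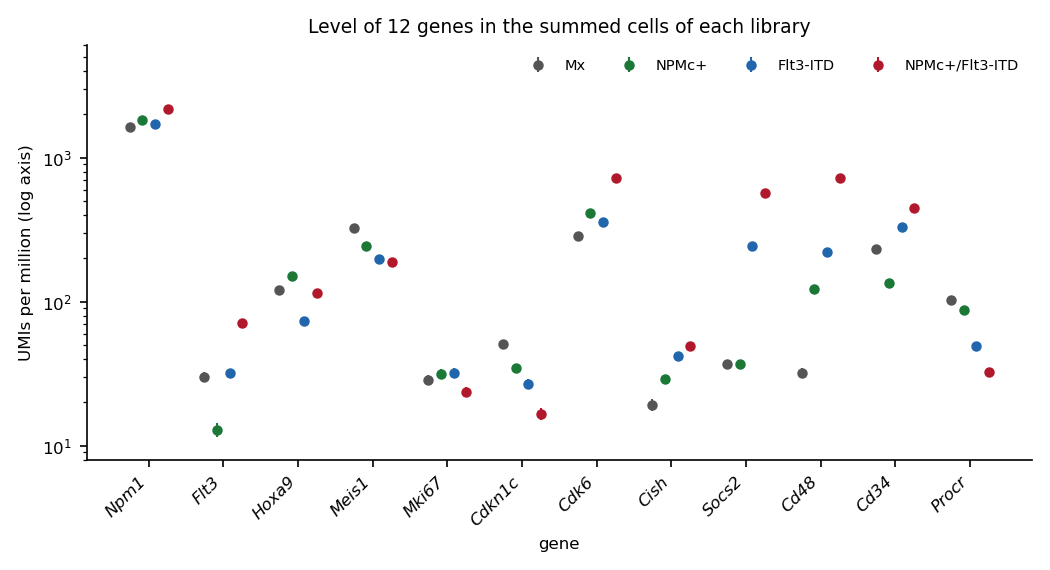
Level of 12 genes (CPM, log axis) in the summed cells of each of the 4 libraries. Points are library sums and bars are 95% counting intervals, mostly smaller than the points; Cd48 runs from 32.0 in Mx to 720.3 in NPMc+/Flt3-ITD and Procr from 102.6 to 32.3.

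NPMc+ stem cells had higher values than Mx cells for many immediate-early, megakaryocyte, erythroid and mitotic genes. The platelet chemokine gene Pf4 was 5.39-fold higher (5.15 to 5.65; 3.09-fold in female cells), the thrombin receptor family gene F2rl2 10.8-fold (8.11 to 14.6) and the platelet glycoprotein gene Gp1bb 4.31-fold (3.76 to 4.95). The stem cell transcription factor gene Hlf was 2.29-fold lower (2.19 to 2.40). Flt3 was 2.33-fold lower (2.04 to 2.67; 1.18-fold in female cells), while Cd48, a surface marker absent from most long-term stem cells, was 3.79-fold higher (3.49 to 4.13). Ranges after fold values here and below are 95% intervals for counting error only, except in the tests on flagged results, where cells or genes were resampled. There was 1 library per genotype, so nothing measures the spread between animals, and genotype and library cannot be parted. Of 6588 genes at the level floor, 117 were at least 2-fold higher and 147 at least 2-fold lower in NPMc+. TMM scaling gave 161 and 98, and a library total without mitochondrial and ribosomal protein genes gave 131 and 247. Leaving out the clusters led by markers of other lineages, the megakaryocyte-like cluster among them, gave 168 and 97. TMM scaling also shifted the median of all genes from -0.01 to 0.15 (log2).

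The highest NPMc+ ratios included Jchain, held by few cells, and genes found more widely. Ms4a3 was found in 40.7% and P2ry1 in 23.2% of the cells of the megakaryocyte-like cluster. At least 3 UMIs of the B cell markers were found in 44.9% of NPMc+ cells. Jchain, which encodes the immunoglobulin joining chain, was 279-fold higher (142 to 647), but 91.6% of its NPMc+ UMIs lay in 1% of the cells; male cells gave 23.5-fold and female cells 23.8-fold. Ighm, the immunoglobulin heavy constant gene, was 146-fold higher (107 to 204; 14.8-fold in male and 53.1-fold in female cells), beside the B cell markers. The granule protease genes Ctsg and Elane were 54.3-fold (32.2 to 99.7) and 41.1-fold higher (23.9 to 77.7), Elane only 6.36-fold in male and 6.10-fold in female cells. Ms4a3, a marker of granulocyte and monocyte progenitors, was 13.8-fold higher (11.7 to 16.5). Serpine2, a protease inhibitor gene, was 6.41-fold higher (4.98 to 8.36; 3.84-fold in female cells) and the purinergic receptor gene P2ry1 5.06-fold (4.04 to 6.41; 7.67-fold in male and 2.08-fold in female cells). At the other end stood neutrophil granule genes carried by few Mx cells. Ngp was 74.2-fold lower (37.4 to 173), but 1.902-fold in female cells and 2.39-fold with the top 1% of cells left out. S100a9 was 31.7-fold lower (23.4 to 44.0; 2.58-fold in female cells) and S100a8 19.2-fold (15.7 to 23.8; 2.99-fold in female cells). The long noncoding RNA gene Rab26os was 6.34-fold lower (5.35 to 7.55; 12.4-fold in female cells), Serpinf1 5.62-fold (5.04 to 6.29), the interferon-inducible GTPase gene Tgtp2 4.00-fold (3.47 to 4.63) and Shisa8 3.83-fold (3.35 to 4.39). Retrocopies of ribosomal protein genes were also among the lowest: Rpl36a-ps1 was 4.76-fold lower, Rpl37rt 3.83-fold, Rpl36-ps2 3.69-fold and Rps27rt 3.54-fold.

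In the G2/M list, 25 of 52 measured members were at least 1.5-fold higher in NPMc+, 1 lower and 26 between. Its median log2 ratio of 0.56 (0.51 to 0.65) lay at percentile 100 of 10000 expression-matched random lists. Examples were the ubiquitin-conjugating enzyme gene Ube2c at 3.63-fold (7.76-fold without its top 1% of cells), the mitotic kinase gene Plk1 at 2.83-fold (5.30-fold without them), Ccnb1 at 2.61-fold and Ccna2 at 2.32-fold. The list's median was 0.25 in female cells. It was 1.32 without the clusters of other lineages, a setting that drops the megakaryocyte-like cluster (55.0% of NPMc+ cells, with 0 cell cycle genes among its leading genes) and so gives cycling cells more weight. The G1/S list did not share this: E2f8 was 1.75-fold higher and Hells 1.62-fold lower, and the median of 49 members was -0.02 (percentile 51.3), or 0.13 under TMM scaling. Of 37 quiescence-associated genes 2 were higher, 5 lower and 30 between, with a median of -0.22 (percentile 0.17) that was -0.02 without those clusters. The cell cycle inhibitor genes Cdkn2c and Cdkn1a were 4.43-fold and 2.62-fold higher, against Tcf7l2 (2.01-fold lower), Ndn (1.995-fold lower) and Cdkn1c, the p57 inhibitor gene (1.47-fold lower). Of 43 LT-HSC identity genes 5 were higher and 11 lower, among them Robo4 (2.43-fold lower) and Hlf, with Sult1a1 2.39-fold higher. The median of -0.23 (percentile 0) turned to 0.13 once the other-lineage clusters were left out.

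Lineage lists set the NPMc+ library apart as well. Of 29 megakaryocyte and platelet genes 18 were higher and 3 lower (median 0.75, percentile 100), with Tuba8 4.43-fold and Clu 3.45-fold higher. Of 18 erythroid genes 11 were higher and 2 lower (0.76, percentile 100), with the metallothionein gene Mt1 3.61-fold and Icam4 3.31-fold higher. Of 19 Hox genes and cofactors 5 were higher and 1 lower (0.20, percentile 99.7): Nkx2-3 was 2.38-fold, Hoxa10 1.77-fold, Hoxa5 1.71-fold and Hoxa9 1.25-fold higher, while Mn1 was 2.46-fold lower and Meis1 1.32-fold lower. Immediate-early and dissociation-stress genes were higher in 20 of 29 (1.09, percentile 100), led by Atf3 (11.6-fold; 20.7-fold without its top cells), Klf2 (6.32-fold) and Btg2 (4.30-fold). Among heat shock genes, 8 of 26 were higher and 0 lower (0.39, percentile 100), led by Hspa1a at 16.9-fold (15.1 to 19.1) and Hspa1b at 9.03-fold, or 29.1-fold and 28.8-fold without the top 1% of cells. Interferon-stimulated genes were lower in 10 of 52 and higher in 1 (-0.32, percentile 0), with Iigp1 2.40-fold and Ifi203 2.08-fold lower. Mitochondrially encoded genes were lower in 8 of 15 (-0.78, percentile 0), mt-Atp6 by 4.74-fold.

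Smaller shifts in NPMc+ included ribosome biogenesis and MYC genes (7 of 48 higher, 1 lower; median 0.29, percentile 100), with the spermidine synthase gene Srm 1.93-fold and Nhp2 1.72-fold higher. The p53 targets had 6 of 22 higher and 3 lower (0.25, percentile 100), with Pmaip1 19.5-fold higher from 8 Mx UMIs. Chromatin and leukemia-associated regulators had 1 of 38 higher and 7 lower (-0.22, percentile 0.08), with Tet1 2.10-fold and Stag2 2.07-fold lower. Adhesion genes had 4 of 26 higher and 9 lower (-0.19, percentile 2.21), with Alcam 2.13-fold lower and Selp 2.02-fold higher. Cell cycle entry genes, 2 of 23 higher and 2 lower, had a median of 0.18 (percentile 98.7), and the antigen presentation list (0 of 21 higher, 3 lower) a median of -0.13 that was 0.01 under TMM scaling. Myeloid genes split into 8 higher and 6 lower of 25, with a median of 0.16 and a mean of -0.00. Not set apart from random lists were lymphoid genes (7 of 22 higher, 5 lower; -0.04, or 0.10 under TMM scaling), STAT5 feedback genes (8 of 25 higher; 0.06), the TGF-beta pathway (3 of 24 higher, 2 lower; -0.20, though Tgfb1 was 2.03-fold higher), NF-kB genes (8 of 30 higher, 6 lower; 0.00, with Cd69 9.13-fold higher), glycolysis genes (4 of 26 higher, 1 lower; 0.09, with Ldha 1.67-fold higher) and oxidative phosphorylation genes (1 of 54 higher, 1 lower; 0.09, with Cycs 1.63-fold higher).

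**Figure D2:**
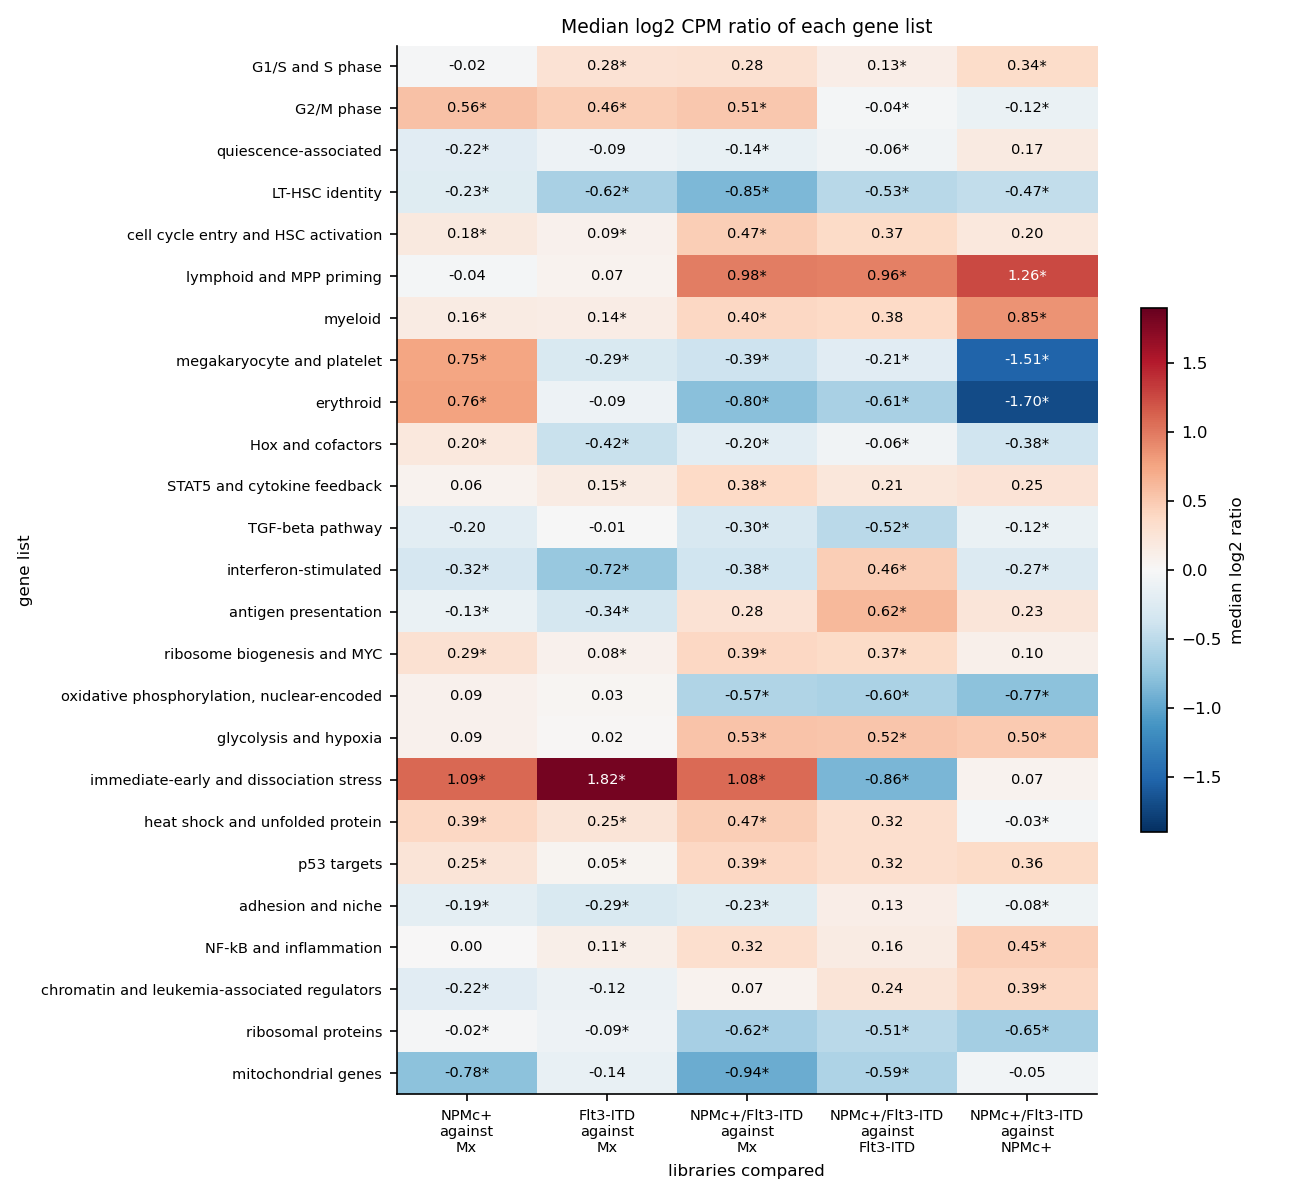
Median log2 CPM ratio of 25 gene lists (vertical axis) in 5 comparisons of libraries (horizontal axis); an asterisk marks a median outside the central 95% of random lists of like expression. Immediate-early genes reach 1.82 in Flt3-ITD against Mx and erythroid genes -1.70 in NPMc+/Flt3-ITD against NPMc+; some medians near 0 take the other sign under TMM scaling, such as G1/S genes in NPMc+ against Mx (-0.02 and 0.13).

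In Flt3-ITD stem cells many immediate-early genes and some cytokine feedback genes stood far above Mx. The stress factor gene Atf3 was 23.2-fold higher (19.6 to 27.8), the zinc finger gene Klf2 16.4-fold (15.6 to 17.1) and the orphan nuclear receptor gene Nr4a1 14.5-fold (13.5 to 15.4). Socs2, a STAT5 target that dampens cytokine signals, was 6.63-fold higher (6.15 to 7.16) and Cd48 6.88-fold (6.35 to 7.48; 4.39-fold in female cells). Some class II antigen presentation genes and some stem cell genes were lower: Cd74, the invariant chain, by 6.26-fold (5.91 to 6.64; 3.03-fold in female cells) and the endothelial protein C receptor gene Procr by 2.08-fold (1.93 to 2.23). Flt3 itself differed little, at 1.06-fold (0.954 to 1.19). Of 6546 genes at the floor 156 were at least 2-fold higher and 114 at least 2-fold lower. TMM scaling gave 192 and 71 and shifted the median of all genes from -0.06 to 0.09. More genes were lower than higher with the total taken without mitochondrial and ribosomal protein genes (173 higher, 184 lower) and with the lower floor (284 and 386).

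The highest Flt3-ITD ratios again included Ctsg at 63.5-fold (37.6 to 117) and Elane at 52.1-fold (30.3 to 98.3; 6.31-fold in male cells). The inhibitors of DNA binding Id1 and Id3 were 22.6-fold (18.1 to 28.4) and 17.5-fold higher (13.7 to 22.6). The chemokine gene Cxcl2 was 19.3-fold higher (15.3 to 24.6; 7.93-fold in female cells), the activation marker Cd69 11.3-fold (10.0 to 12.9; 4.95-fold in female cells), Cdkn1a 10.4-fold (9.41 to 11.6), Rgcc 9.95-fold (9.17 to 10.8) and Klf4 9.55-fold (8.67 to 10.5). Tgtp2 was 8.50-fold lower (6.91 to 10.6), H2-Eb1 6.46-fold (5.82 to 7.19; 2.82-fold in female cells) and H2-Aa 4.87-fold (4.54 to 5.22; 2.54-fold in female cells). Meg3, an imprinted long noncoding RNA gene, was 5.63-fold lower (4.64 to 6.88; 9.16-fold in male and 2.05-fold in female cells), Tnip3 5.25-fold (4.50 to 6.15; 9.16-fold and 2.47-fold) and the multimerin gene Mmrn1 4.02-fold (3.61 to 4.48; 7.75-fold and 2.27-fold). Iigp1 was 3.98-fold lower (3.58 to 4.43; 2.27-fold in female cells), Rsrp1 3.597-fold, Rpl36a-ps1 3.50-fold and Clec1a 3.43-fold (7.71-fold in male and 1.88-fold in female cells). Ngp was 4.65-fold lower in all cells and 43.1-fold lower in male cells, but higher in female cells (log2 ratio 3.19).

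Of 29 immediate-early genes 27 were at least 1.5-fold higher in Flt3-ITD and 0 lower, with a median log2 ratio of 1.82 (1.81 to 1.88, percentile 100). STAT5 and cytokine feedback genes split into 10 of 25 higher and 3 lower (0.15, percentile 99.98), with the phosphatase gene Dusp5 9.25-fold, the cytokine gene Osm 8.37-fold, Socs3 5.99-fold and Cish 2.19-fold higher. Of 22 p53 targets 7 were higher and 1 lower (0.05, percentile 98.8; -0.02 in female cells), with Gdf15 9.45-fold and Btg2 8.47-fold higher, and of 30 NF-kB genes 7 were higher and 4 lower (0.11, percentile 99.96), with Tnfaip3 9.02-fold (4.42-fold in female cells) and Cebpb 3.96-fold higher. The interferon-stimulated list was the most uniformly lower, 34 of 52 members against 0 higher (-0.72, percentile 0), among them Gbp4 at 4.43-fold (11.5-fold in male and 2.45-fold in female cells), Irgm2 at 4.13-fold (2.72-fold in female cells) and Ifi44 at 3.33-fold. Antigen presentation genes were lower in 6 of 21 and higher in 0 (-0.34, percentile 0). LT-HSC identity genes were lower in 22 of 43 and higher in 1 (-0.62, percentile 0), among them Sult1a1 (3.27-fold), the N-myc gene Mycn (2.51-fold) and Mllt3 (2.501-fold). Of 19 Hox genes and cofactors 8 were lower and 0 higher (-0.42, percentile 0.02): Hoxa3 by 2.60-fold, Hoxb2 by 2.29-fold, Meis1 by 1.64-fold and Hoxa9 by 1.63-fold. Megakaryocyte genes were lower in 7 of 29 and higher in 2 (-0.29, percentile 0.03), with Aldh1a1 2.62-fold lower (4.16-fold in male cells) and Plek 2.45-fold higher, and adhesion genes lower in 7 of 26 and higher in 1 (-0.29, percentile 0.06).

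Proliferation lists in Flt3-ITD were higher for both phases. Of 52 G2/M genes 20 were higher and 0 lower (0.46, percentile 100), with Ube2c 2.17-fold (3.602-fold in male cells), Nuf2 1.94-fold (3.01-fold without its top cells) and Cks2 1.91-fold higher, and of 49 G1/S genes 2 were higher and 0 lower (0.28, percentile 100), Rrm2 by 1.72-fold and Cdc45 by 1.58-fold. Mki67 was 1.13-fold higher (1.01 to 1.26). The quiescence list was not set apart (7 of 37 higher, 4 lower; -0.09, or 0.05 under TMM scaling), holding both Skil, 3.06-fold higher, and Txnip, 2.75-fold lower (1.76-fold in female cells). Myeloid genes had 11 of 25 higher and 4 lower (0.14, percentile 99.98), with the myeloperoxidase gene Mpo 8.80-fold and Cebpa 2.71-fold higher. Heat shock genes had 3 of 26 higher and 1 lower (0.25, percentile 100), Hspa1a at 2.46-fold. Cell cycle entry genes (2 of 23 higher, 2 lower; 0.09, percentile 98.1) and ribosome biogenesis genes (1 of 48 higher; 0.08, percentile 98.9), where the ornithine decarboxylase gene Odc1 was 2.08-fold higher, were weakly set apart. Lymphoid and MPP genes were not (5 of 22 higher, 2 lower; 0.07, percentile 96.4), although Dntt, the terminal transferase gene, was 13.9-fold and Plac8 2.25-fold higher.

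NPMc+/Flt3-ITD cells combined high progenitor and cytokine feedback genes with low stem cell, ribosomal protein and respiratory chain genes. Cd48 was 22.5-fold above Mx (20.9 to 24.4; 11.3-fold in female cells), Socs2 15.4-fold (14.3 to 16.5; 7.05-fold in female cells), Cdk6, a kinase gene tied to stem cell exit from quiescence, 2.51-fold (2.44 to 2.59) and Flt3 2.37-fold (2.16 to 2.60; 1.22-fold in female cells). Procr was 3.18-fold lower (2.94 to 3.44; 1.58-fold in female cells) and Cdkn1c 3.09-fold (2.76 to 3.46). The ribosomal protein gene Rpl27 was 6.02-fold lower (5.88 to 6.16). Of 6938 genes at the floor 376 were at least 2-fold higher and 398 at least 2-fold lower. The median log2 ratio of all genes was 0.21, so list medians in this library stand beside those of random lists, and it was -0.02 with the total taken without mitochondrial and ribosomal protein genes, which gave 347 higher and 644 lower.

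Some lymphoid and T-lineage transcripts were among the high ratios over Mx, several against very few Mx UMIs. Tcrg-C1, a T cell receptor gamma constant gene, was 164-fold higher (126 to 218; 490-fold in male cells) and Tcrg-C4 199-fold (130 to 321; 53.9-fold in female cells). Tcrg-C2 (630 to 138800), Ly6d (281 to 61970) and the granzyme gene Gzma (166 to 36660) had counting intervals that wide because each rested on 1 Mx UMI. Dntt was 199-fold higher (139 to 298; 27.0-fold in female cells), the thymocyte signalling gene Themis 159-fold (68.0 to 491) from 5 Mx UMIs, and Gzmb 169-fold (91.6 to 352; 26.0-fold in female cells). The growth factor gene Gdf10 and the basophil protease gene Mcpt8, both with 0 UMIs in Mx, were at least 265-fold and at least 175-fold higher. Igfbp7 was 464-fold higher (252 to 968; 57.3-fold in female cells) and Ctsg 260-fold (155 to 476; 70.1-fold in female cells). The lowest values were Meg3, at least 283-fold lower with 0 UMIs in NPMc+/Flt3-ITD, and the imprinted gene Ndn, 112-fold lower (50.9 to 306; 10.6-fold in female cells). Fhl1 was 44.0-fold lower (26.4 to 79.1; 4.36-fold in female cells), Mmrn1 29.3-fold (23.1 to 37.6; 3.99-fold), Grb10 28.1-fold (19.5 to 41.9; 4.21-fold), Bex1 20.9-fold (16.5 to 27.0; 2.93-fold) and Wdr89 19.7-fold (18.4 to 20.97). Ribosomal protein retrocopies were again low: Rpl36a-ps1 56.9-fold, Rpl36-ps2 32.4-fold, Rpl37rt 32.3-fold, Rps15a-ps5 31.7-fold and Rps27rt 25.3-fold.

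Of 94 genes in the ribosomal protein list 48 were at least 1.5-fold lower than in Mx, 1 higher and 45 between, with a median log2 ratio of -0.62 (-0.64 to -0.62) against 0.26 for random lists. Without 8 members that encode no ribosomal protein, 48 of 86 were lower (-0.78). Rpl36al was 6.91-fold, Rps28 6.53-fold and Rpl24 5.53-fold lower, and ribosomal protein genes made up 21.1% of this library's UMIs against 30.9% in Mx, 29.4% in NPMc+ and 28.9% in Flt3-ITD. Against Mx, the list's median was near 0 in the single mutants: -0.02 in NPMc+ (2 of 94 lower, 1 higher) and -0.09 in Flt3-ITD (2 lower, 2 higher), or 0.12 and 0.05 under TMM scaling. Both medians still lay below those of random lists, at percentile 0.08 in NPMc+ (random median 0.07) and 0 in Flt3-ITD (random median 0.03). Nuclear oxidative phosphorylation genes were lower in 27 of 54 and higher in 2 (-0.57, percentile 0), among them Ndufb4 (8.82-fold; 5.01-fold in female cells), Atp5l (5.14-fold) and Cox6c (2.90-fold). Their Flt3-ITD median over Mx was 0.03, with 1 member higher, or -0.01 with the total taken without mitochondrial and ribosomal protein genes. Mitochondrially encoded genes were lower in 10 of 15 and higher in 2 (-0.94, percentile 0), mt-Atp6 by 11.9-fold, yet their summed level was 8272 CPM against 7331 in Mx, with mt-Nd1 at 2241 against 1341 CPM. In Flt3-ITD the list was lower in 7 of 15 (-0.14, or 0.01 under TMM scaling). Glycolysis genes went the other way, 8 of 26 higher and 1 lower (0.53, percentile 100), with Egln3 4.44-fold higher (1.84-fold in female cells) and Eno1 2.07-fold higher, but Hk2 2.86-fold lower. The same list had 3 of 26 higher in Flt3-ITD over Mx (0.02, or -0.02 with that total).

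Stem cell programs were low in the double mutant library: 24 of 43 LT-HSC identity genes were lower and 3 higher (-0.85, percentile 0; -1.20 to -0.35 over the alternatives), among them the angiopoietin receptor gene Tek at 15.4-fold (1.88-fold in female cells), Sult1a1 at 9.48-fold (2.15-fold) and Tgm2 at 6.42-fold (1.67-fold). Quiescence genes were lower in 9 of 37 and higher in 5 (-0.14, percentile 0.02), with Cdkn1a 7.42-fold and Cdkn2c 5.94-fold higher, or 2.82-fold and 3.28-fold in female cells. Lymphoid and MPP genes were higher in 15 of 22 and lower in 3 (0.98, percentile 100), with Ighm 73.5-fold (25.3-fold in female cells), Tespa1 9.33-fold (5.05-fold) and Plac8 5.60-fold higher. The lymphoid median ran from 0.281 to 1.01 over the alternatives, at its lower end near the 0.21 of all genes in the main setting. Myeloid genes were higher in 12 of 25 and lower in 4 (0.40, percentile 99.4), with Clec12a 36.6-fold (12.9-fold in female cells) and Elane 23.9-fold (4.04-fold) higher. The STAT5 list had 10 of 25 higher and 4 lower (0.38, percentile 97.9), with Osm 20.4-fold and Pim2 5.83-fold higher, and cell cycle entry genes 10 of 23 higher and 2 lower (0.47, percentile 99.7). Erythroid genes were lower in 10 of 18 (-0.80, percentile 0) and megakaryocyte genes in 12 of 29, with 3 higher (-0.39, percentile 0), but in female cells the medians were 0.83 and 0.49. Of this library's 179 female cells 10 lay in the erythroid-like and 10 in the megakaryocyte-like cluster, which held 5 of its 2425 male cells. Whether these few cells account for the female medians was not tested. The apolipoprotein gene Apoe, 4.50-fold lower (4.36 to 4.64) in all cells, stood at 128.9 CPM in the male and 896.1 CPM in the female cells of the double mutant library.

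Further lists in the double mutant library over Mx were G2/M genes (18 of 52 higher, 0 lower; 0.51, percentile 100), with Smc4 2.57-fold (1.63-fold without the T-lineage, erythroid and T or NK clusters) and Ccnb2 2.43-fold higher, and immediate-early genes (19 of 29 higher; 1.08, percentile 100), with Klf2 7.96-fold higher. Interferon-stimulated genes were lower in 22 of 52 and higher in 3 (-0.38, percentile 0; 0.03 in female cells), with Ifi44 6.65-fold and Ifit1 5.14-fold lower. Hox genes were lower in 6 of 19 and higher in 3 (-0.20, percentile 0.62; 0.01 in female cells), with Hoxb2 11.8-fold lower (1.86-fold in female cells) and Hoxa9 near Mx at 0.955-fold. TGF-beta genes were lower in 7 of 24 and higher in 6 (-0.30, percentile 0.07; 0.11 with the higher floor on gene level), adhesion genes lower in 11 of 26 and higher in 6 (-0.23, percentile 0.1; 0.03 in female cells and 0.02 with the higher floor). Ribosome biogenesis genes were higher in 9 of 48 and lower in 2 (0.39, percentile 98.95), p53 targets higher in 8 of 22 and lower in 1 (0.39, percentile 99.5) and heat shock genes higher in 7 of 26 and lower in 2 (0.47, percentile 99.8), with the unfolded protein response gene Xbp1 3.40-fold higher. The G1/S, antigen presentation, NF-kB and chromatin lists had medians of 0.28, 0.28, 0.32 and 0.07, inside the range of random lists, the last being -0.12 with the total taken without mitochondrial and ribosomal protein genes.

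**Figure D3:**
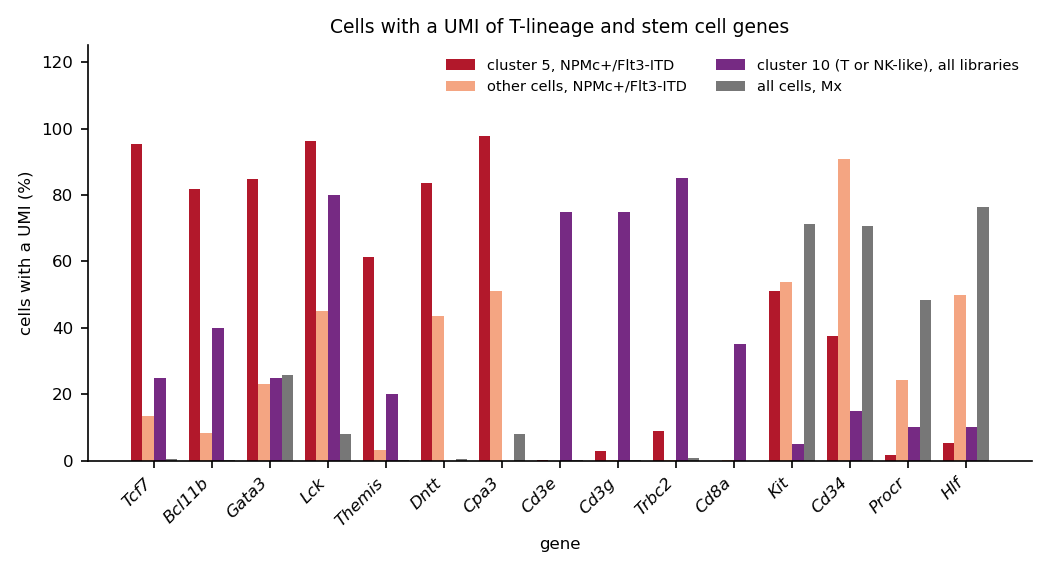
Percent of cells with at least 1 UMI of 15 T-lineage and stem cell genes (horizontal axis) in the T-lineage cluster and the other cells of NPMc+/Flt3-ITD, in the mature T or NK-like cells of all libraries and in all Mx cells. Tcf7 is found in 95.4% of the first group and 0.476% of Mx cells, and Cd3e in 0.263% of the first group and 75% of the mature T or NK-like cells.

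The T-lineage cluster of the double mutant library carried early T-lineage transcripts. Its levels of Cd3e, Cd3d, Cd3g and Trbc2 lay far below those of the mature T or NK-like cells. The genes here were chosen after their values were seen. In its cells Tcf7, the gene for the T cell factor TCF1, stood at 1146 CPM, Lck at 751.8, Gata3 at 531 and Bcl11b, a T-lineage commitment gene, at 511.3, against 23.3, 85.2, 32.3 and 12.96 CPM in the library's other 2559 cells. Background detection in Mx was 0.476% of cells for Tcf7, 7.94% for Lck, 25.7% for Gata3 and 0.278% for Bcl11b, against 95.4%, 96.2%, 84.8% and 81.8% in the cluster. Cd3e was found in 0.263% of these cells, Cd3g in 2.76% and Cd8a in 0%. Cd3e, Cd3d, Cd3g and Trbc2 summed to 36.3 CPM, above the 1.83 CPM of the library's other cells, and Trbc2 was found in 8.92% against 0.313% of cells, and in 85% of the mature T or NK-like cells. The mast cell carboxypeptidase gene Cpa3 stood at 2742 CPM against 161.9 in the other cells, Dntt at 1001 against 147.7, Il7r at 57.3 against 1.004 and Kit at 157.2 against 96.5. Kit was found in 51.05% against 53.9% of cells. Other progenitor genes were lower in the cluster: Cd34 (139.7 against 502 CPM), Flt3 (23.7 against 79.2 CPM) and Cd48 (277.8 against 798.6 CPM). Rag1 was found in 0.787% of its cells. The stem cell genes Hlf (10.9 against 104.7 CPM) and Procr (3.45 against 37.4 CPM) and the proliferation gene Mki67 (1.71% against 11.4% of cells) were lower in the cluster. The Mki67 difference is partly set by the clustering, which put 298 cells of this library into a cell cycle cluster that counts among the other cells. These shares were also not thinned, at a median of 4714 UMIs per cell in the cluster against 8228 in the others.

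NPMc+ on top of Flt3-ITD, read as NPMc+/Flt3-ITD over Flt3-ITD, went with higher lymphoid and antigen presentation genes and lower immediate-early and ribosomal protein genes. Tcf7 was 235-fold higher (148 to 396) and Bcl11b 129-fold (77.9 to 230), or 46.4-fold and 40.7-fold without the T-lineage, erythroid and T or NK clusters. Mycn was 6.04-fold higher (5.66 to 6.45; 3.73-fold in female cells), Cdk6 2.004-fold (1.95 to 2.06) and Cd74 3.73-fold (3.51 to 3.96; 6.16-fold in female cells). Nr4a1 was 6.85-fold lower (6.57 to 7.15) and Procr 1.53-fold (1.40 to 1.68). Of 6746 genes at the floor 289 were at least 2-fold higher and 301 at least 2-fold lower; TMM scaling gave 216 and 381 and moved the median of all genes from 0.28 to 0.10. Without the T-lineage, erythroid and T or NK clusters the counts were 225 and 293.

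Among the other highest ratios were Themis at 209-fold (81.3 to 768), Arpp21 at 196-fold (83.6 to 604; 15.3-fold in female cells), Gzma at 139-fold, Tcrg-C2 at 137-fold (3.23-fold in female cells), Tcrg-C4 at 118-fold (6.11-fold), Tcrg-C1 at 91.1-fold (25.5-fold), Ly6d at 68.6-fold, Gstp3 at 34.0-fold and Skap1 at 31.1-fold (4.16-fold). Gdf10 rested on 1 UMI in Flt3-ITD (149 to 32970). The lowest were the retrocopies Rpl36a-ps1 (16.2-fold), Rpl37rt (11.4-fold), Rps15a-ps5 (11.1-fold), Rpl36-ps2 (11.0-fold), Rps27rt (9.44-fold), Rps25-ps1 (8.20-fold) and Rps13-ps2 (8.12-fold). With them stood Bex1 (13.6-fold; 2.80-fold in female cells), Id3 (10.8-fold), and the histone genes Hist2h2aa1 (10.4-fold) and Hist1h2ap (9.41-fold; 5.55-fold in female cells). Lymphoid and MPP genes were higher in 15 of 22 and lower in 1 (0.96, percentile 100), with the chromatin organizer gene Satb1 6.62-fold higher, or 1.51-fold without the T-lineage, erythroid and T or NK clusters. Over the alternatives the lymphoid median ran from 0.219 to 1.15, at its lower end near the 0.28 of all genes in the main setting. Antigen presentation genes were higher in 12 of 21 (0.62, percentile 100), H2-Eb1 by 4.52-fold (7.85-fold in female cells) and H2-Aa by 3.40-fold, and interferon-stimulated genes in 20 of 52, with 3 lower (0.46, percentile 100), Igtp by 2.75-fold (4.32-fold in female cells). Immediate-early genes were lower in 21 of 29 (-0.86, percentile 0), Maff by 6.99-fold and Atf3 by 6.09-fold, and TGF-beta genes lower in 11 of 24 and higher in 2 (-0.52, percentile 0), Id1 by 6.04-fold.

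LT-HSC identity genes were lower in 19 of 43 and higher in 3 (-0.53, percentile 0; -0.71 to -0.155 over the alternatives) in this comparison, ribosomal protein genes lower in 45 of 94 (-0.51) and oxidative phosphorylation genes lower in 29 of 54 and higher in 1 (-0.60). The G2/M median of -0.04 (3 of 52 higher) lay at percentile 0, below the 0.24 of random lists, yet was 0.13 without the clusters of other lineages and 0.48 in female cells. The G1/S median of 0.13 (0 of 49 beyond 1.5-fold) lay at percentile 0.85, also below random lists (0.26), and was -0.04 under TMM scaling, which shifts all ratios alike. Quiescence genes had 5 of 37 higher and 8 lower (-0.06, percentile 0) and Hox genes 5 of 19 higher and 5 lower (-0.06, percentile 0.23; 0.40 in female cells and 0.09 with the higher floor), Hoxa9 being 1.56-fold higher. Erythroid genes were lower in 10 of 18 (-0.61; 0.95 in female cells) and megakaryocyte genes in 13 of 29 (-0.21; 0.57 in female cells). Glycolysis genes had 6 of 26 higher (0.52, percentile 100) and ribosome biogenesis genes 4 of 48 (0.37, percentile 99.4).

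Flt3-ITD on top of NPMc+, read as NPMc+/Flt3-ITD over NPMc+, went with higher lymphoid genes and lower megakaryocyte and erythroid genes. The STAT5 and cytokine feedback list was not set apart (9 of 25 higher, 7 lower; 0.25, percentile 75.6), though Socs2 was 15.3-fold higher (14.3 to 16.4; 7.71-fold in female cells), Cd48 5.93-fold (5.71 to 6.17; 2.56-fold), Flt3 5.52-fold (4.90 to 6.23; 1.44-fold) and Cd34 3.31-fold (3.19 to 3.44; 1.54-fold). Pf4 was 15.4-fold lower (14.5 to 16.5; 3.53-fold in female cells) and Procr 2.73-fold lower (2.52 to 2.95; 1.48-fold in female cells). The highest ratios were those of Themis and Gdf10, at least 318-fold and at least 317-fold with 0 UMIs in NPMc+, Tcrg-C1 (250-fold), Tcrg-C4 (227-fold), Sparc (207-fold; 19.2-fold in female cells) and Tcrg-C2 (191-fold). Meg3, with 0 UMIs in the double mutant library, was at least 346-fold lower, Jchain 262-fold (26.6-fold in male and 21.2-fold in female cells), the cyclin gene Ccnd1 28.8-fold (3.26-fold in female cells), Wfdc17 25.8-fold and Sult1a1 22.7-fold (3.595-fold in female cells). Of 6770 genes 373 were at least 2-fold higher and 311 lower; TMM scaling gave 285 and 385 and moved the median of all genes from 0.22 to 0.04.

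Megakaryocyte genes were lower in 21 of 29 (-1.51, percentile 0), Cavin2 by 15.4-fold (1.29-fold in female cells), and erythroid genes in 13 of 18 (-1.70, percentile 0; 0.34 in female cells), Apoe by 8.90-fold (1.80-fold). The megakaryocyte median ran from -1.77 to -0.002 over the alternatives, so it was lost in at least 1 of them. Lymphoid genes were higher in 16 of 22 (1.26, percentile 100), Dntt by 110-fold (12.8-fold in female cells) and Satb1 by 9.54-fold (1.46-fold), and myeloid genes in 13 of 25, with 5 lower (0.85, percentile 100; -0.13 in female cells). The lymphoid median ran from 0.214 to 1.57 over the alternatives, at its lower end near the 0.22 of all genes in the main setting. NF-kB genes had 12 of 30 higher (0.45, percentile 100) and chromatin regulators 9 of 38 (0.39, percentile 99.9), with Dnmt3b 2.32-fold higher. G1/S genes had 5 of 49 higher and 1 lower (0.34, percentile 99.2), while the G2/M median was -0.12 (percentile 0), or 0.07 with cells thinned to 3000 UMIs. LT-HSC identity genes were lower in 19 of 43 and higher in 6 (-0.47, percentile 0; -0.70 to -0.095 over the alternatives), ribosomal protein genes lower in 50 of 94 (-0.65), oxidative phosphorylation genes lower in 31 of 54 (-0.77) and Hox genes lower in 7 of 19 (-0.38, percentile 0). Heat shock genes were close to level (-0.03, percentile 1.54; 0.22 in female cells), but Hspa1a was 6.14-fold lower (1.34-fold in female cells).

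Ratios for a mutation without and with the other mutation were weakly related across 6256 genes, which are not independent replicates. For NPMc+ the Pearson correlation was 0.17 (counting range 0.154 to 0.192; 0.147 to 0.352 over the alternatives) and the Spearman correlation 0.15. The Pearson correlation was -0.00214 in simulated libraries that differed by counting noise alone. That value cannot show whether real differences are shared, since no gene differed in the simulation. Genes at least 2-fold higher in both backgrounds numbered 32, against 3.07 if independent, lower in both 39 against 4.33, and opposite 25 against 7.59. For Flt3-ITD the correlations were 0.14 (0.083 to 0.303 over the alternatives) and 0.13, with 41 genes higher in both against 5.96, 38 lower against 2.97 and 25 opposite against 9.39.

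**Figure D4:**
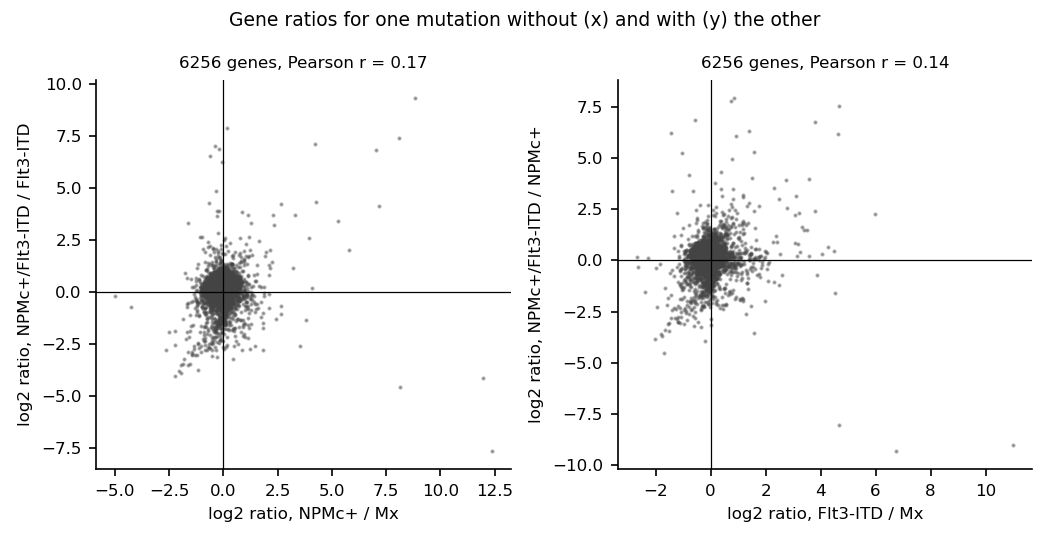
Log2 CPM ratios of 6256 genes for NPMc+ (first panel) and Flt3-ITD (second panel) without the other mutation (horizontal axis) and with it (vertical axis), each point a gene. The clouds show weak relations, with Pearson correlations of 0.17 and 0.14.

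Shares of cells with a proliferation transcript were read after every cell was thinned to 3000 UMIs. Mki67, which encodes a nuclear protein of cycling cells, was found in 3.81% of Mx (3.07 to 4.67%), 5.69% of NPMc+ (4.77 to 6.73%), 5.56% of Flt3-ITD (4.64 to 6.61%) and 3.85% of NPMc+/Flt3-ITD cells (3.19 to 4.60%). Without thinning its shares were 8.65%, 14.6%, 13.2% and 9.15%. Top2a, the mitotic topoisomerase gene, was found in 11.2%, 12.04%, 12.7% and 13.2% of thinned cells. Clusters led by cell cycle genes held 18.0% of Mx, 7.58% of NPMc+, 6.52% of Flt3-ITD and 9.70% of NPMc+/Flt3-ITD cells, but 3.22%, 7.66%, 6.39% and 2.77% at a clustering resolution of 0.3. At resolution 1.0 they held 18.7%, 7.79%, 23.2% and 14.1%, so the order of the libraries depended on the setting. At least 3 UMIs of the G2/M list were present in 93.7%, 95.7%, 96.8% and 98.7% of cells, a measure near its ceiling, and at least 5 UMIs in 74.7%, 79.7%, 83.6% and 91.6%. All of these cells had been sorted as long-term stem cells.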

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

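Of the tests in this part, those on UMI depth, free RNA, doublets, a single animal, few cells, the sexes and isolation stress were chosen only after the result was seen; those on gene copies, short transcripts and mature T cells were written down earlier. The tests on UMI depth, free RNA and few cells took the place of others whose outcome the clustering, the thinning or the choice of gene had fixed. All of them used the same data in which the patterns were found, so every reading here is a hypothesis.

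Ribosomal protein and respiratory chain genes had lower values in NPMc+/Flt3-ITD. A difference in UMIs per cell was argued against. The ribosomal protein median over Mx was -0.62 (-0.64 to -0.60) in 2389 draws of cells, with replacement, from each library, matched for UMIs. The median of all genes was 0.21. This matching does not test read mapping. Reads shared with near-identical gene copies cannot be told apart from a change in the genes themselves: 58 members without shared sequence lay -0.45 (range -0.89 to -0.23) from genes outside the lists, a range that reaches values the copies could explain, and the Spearman correlation of the ratio with the shared portion was -0.22. Poorer recovery of short transcripts might also contribute and is not excluded, because 338 other genes with transcripts of at most 906 bases lay -0.18 (-0.32 to -0.09) from longer genes, a range that crosses the bound set beforehand. The Mx library may differ technically as well. The retrocopies Rps27rt, Rpl37rt and Rpl36a-ps1 were among the leading genes of the cluster that held most Mx cells. Rpl36a-ps1 was also lower than in Mx in both single mutants. A technical difference of Mx would touch every ratio over Mx and was not tested. The ribosomal protein and respiratory chain medians were also lower over Flt3-ITD and over NPMc+, comparisons without Mx. The genotype and a technical difference of the NPMc+/Flt3-ITD library both stay open.

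T-lineage transcripts filled a cluster with 22.9% of NPMc+/Flt3-ITD cells. Free RNA was argued against without use of clusters: Bcl11b, Themis, Lck and Gata3 summed to 8.42-fold (7.70 to 9.15) in the library's cells with a Tcf7 UMI over those with none. Mature T cells were argued against, on Cd3e, Cd3d, Cd3g and Trbc2 alone, by a ratio of 0.0117 against the mature T or NK-like cells. Those cells had been named by markers that include these genes, so the level there is high by selection. Trbc1 and Trdc, also T cell receptor genes, were not in the ratio and were found in 87.65% and 76.3% of the cluster's cells. Doublets were argued against by a median UMI ratio of 0.573 (4713.5 against 8228). Cells of a single animal could account for the cluster and cannot be told apart from the genotype: 2 female and 589 male cells lay in it, against 177 female and 1836 male cells in the rest, so it held 24.3% of the male and 1.12% of the female cells. The sex call keeps the test open, since it cannot separate the male animals of a pool from each other and the rest of the library was mostly male too, and contents of the sort gate that differ with the genotype were not tested.

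Immediate-early genes had higher values in Flt3-ITD. A few cells holding the transcripts were argued against: the median over all 29 members was 1.67 (1.42 to 2.15) in the 1914 of 2393 Flt3-ITD cells poorest in the other members, against 1.82 in all cells. A difference between the sexes of the pool was argued against by medians of 1.78 in female and 1.81 in male cells. Stress during isolation may underlie the values and cannot be told apart from the genotype: the heat shock genes Hspa1a, Hspa1b, Dnajb1 and Hsph1 had a median of 0.92, yet 2.11 in NPMc+ and 0.77 in NPMc+/Flt3-ITD. A single library per genotype keeps this open.

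Several lists were picked out because their median log2 ratio for a mutation was set apart from random lists and took the opposite sign beside the other mutation; the difference was not tested. The median of all genes was 0.28 over Flt3-ITD and 0.22 over NPMc+ in the double mutant library. For NPMc+, the median without and with Flt3-ITD was 0.56 and -0.04 for G2/M genes (difference -0.60), 0.75 and -0.21 for megakaryocyte genes (-0.96), 0.76 and -0.61 for erythroid genes (-1.37) and 0.20 and -0.06 for Hox genes (-0.26). It was -0.32 and 0.46 for interferon-stimulated genes (0.78), -0.13 and 0.62 for antigen presentation genes (0.76) and 1.09 and -0.86 for immediate-early genes (-1.95). For Flt3-ITD, the median without and with NPMc+ was 0.46 and -0.12 for G2/M genes (-0.58) and 0.25 and -0.03 for heat shock genes (-0.28). Several opposite signs were lost in other settings. Over Flt3-ITD, G2/M was 0.13 without clusters of other lineages, 0.037 with the mean of CPM per cell, 0.072 with thinned cells and 0.48 in female cells, Hox 0.085 with the higher floor on gene level and 0.40 in female cells, and erythroid and megakaryocyte genes 0.95 and 0.57 in female cells. Over NPMc+, G2/M was 0.072 with thinned cells and 0.565 in female cells, and heat shock 0.039 without clusters of other lineages and 0.22 in female cells. Antigen presentation in NPMc+ over Mx was 0.05 without those clusters.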

How the results depend on the processing

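With 1 library per genotype, there was no replicate to leave out. No paired analysis was possible because the libraries share no animals. Of 4078 alternative values for 328 results, 37 reversed the sign of a called value, 18 of them with female cells alone. Random lists were drawn in the main setting only, so a reversed sign does not say on which side of random lists a median would lie. A value counts as reversed here only if the main value was called: a list median set apart from random lists, or a named gene at least 1.5-fold higher or lower. Another 55 alternative values took the other sign where the main value was not called, 11 of them under TMM scaling. Among the 38 main results 252 alternative values stayed the same, 107 moved and 5 reversed; among the others 2419 stayed the same, 1263 moved and 32 reversed. Of 2076 values for named genes 2 reversed. The settings with male cells, with female cells, without the top 1% of cells of each gene, and without the T-lineage, erythroid and T or NK clusters were chosen after the data had been seen. In all of the following the cause was not tested, except where an effect is said to follow by construction; a lower or higher floor counts more or fewer genes in that way. Values for lists are median log2 ratios.

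With the lower floor on gene level, the genes at least 2-fold higher and lower numbered 224 and 483 in NPMc+ against Mx, 284 and 386 in Flt3-ITD against Mx, 671 and 880.0 in NPMc+/Flt3-ITD against Mx, and 603 and 590.0 in NPMc+/Flt3-ITD against Flt3-ITD. The correlation of the Flt3-ITD ratios was 0.20. With the higher floor those numbers were 65 and 56, 96 and 52, and 225 and 233 against Mx, and 152 higher against Flt3-ITD. G2/M was 0.67 in NPMc+ and 0.545 in NPMc+/Flt3-ITD over Mx, quiescence -0.064 in NPMc+/Flt3-ITD over Mx, and the correlations were 0.147 for NPMc+ and 0.107 for Flt3-ITD. The higher floor reversed Hox (0.085) and mitochondrial genes (0.071) over Flt3-ITD, TGF-beta (0.11) and adhesion (0.022) over Mx, and interferon (0.097) over NPMc+, all in NPMc+/Flt3-ITD.

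TMM scaling shifts all ratios of a comparison alike, so a median near 0 takes the other sign by construction where the shift points that way, and this says nothing about a list relative to other genes. With it, 71 genes were lower in Flt3-ITD against Mx. G2/M was 0.703 in NPMc+ and 0.605 in Flt3-ITD over Mx and -0.22 in NPMc+/Flt3-ITD over Flt3-ITD. Quiescence was -0.073 in NPMc+, 0.053 in Flt3-ITD (-0.09 in the main setting, not called) and -0.23 in NPMc+/Flt3-ITD over Flt3-ITD. Of called medians it reversed the sign of G1/S in NPMc+/Flt3-ITD over Flt3-ITD (-0.041), antigen presentation in NPMc+ (0.01) and ribosomal proteins in NPMc+ (0.119) and Flt3-ITD (0.051). G1/S had been called for lying below random lists (0.13 against 0.26, percentile 0.85), so a negative sign does not go against its call. With the total taken without mitochondrial and ribosomal protein genes, genes lower than in Mx numbered 247 in NPMc+, 184 in Flt3-ITD and 644 in NPMc+/Flt3-ITD. In NPMc+/Flt3-ITD G2/M was 0.33 over Mx and -0.195 over Flt3-ITD, quiescence -0.34 and -0.21, and G1/S reversed in sign over Flt3-ITD (-0.021). This total also shifts all ratios of a comparison alike (over Flt3-ITD the median of all genes was 0.28 in the main setting and 0.12 here). That sign change therefore follows by construction as well.

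Leaving out the clusters led by markers of other lineages removes the megakaryocyte-like cluster, 55.0% of NPMc+ cells, and so gives the cycling cells of that library more weight by construction. The same setting removes the T-lineage cluster, 22.9% of NPMc+/Flt3-ITD cells, and the erythroid-like and T or NK-like clusters. Without these clusters, 97 genes were lower in NPMc+ against Mx. G2/M was 1.32 in NPMc+ and 0.65 in NPMc+/Flt3-ITD over Mx and reversed to 0.13 over Flt3-ITD. Quiescence was -0.02 in NPMc+ and -0.099 in NPMc+/Flt3-ITD over Flt3-ITD. LT-HSC identity (0.13) and antigen presentation (0.05) reversed in NPMc+ over Mx and heat shock (0.039) in NPMc+/Flt3-ITD over NPMc+. The correlations were 0.231 for NPMc+ and 0.303 for Flt3-ITD. Without the T-lineage, erythroid and T or NK clusters, G2/M in NPMc+/Flt3-ITD was 0.66 over Mx and reversed to 0.126 over Flt3-ITD, quiescence was -0.101 over Flt3-ITD, heat shock reversed over NPMc+ (0.012) and the NPMc+ correlation was 0.193.

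With the mean of CPM per cell, G2/M in NPMc+/Flt3-ITD was 0.61 over Mx and reversed to 0.037 over Flt3-ITD, quiescence was -0.23 over Mx, and the correlations were 0.239 and 0.238. With cells thinned to a single depth, G2/M reversed in NPMc+/Flt3-ITD over Flt3-ITD (0.072) and over NPMc+ (0.072), quiescence was -0.113 in NPMc+ and -0.067 in Flt3-ITD over Mx, and the correlations were 0.201 and 0.190. All barcodes as deposited gave correlations of 0.20 and 0.167.

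In male cells G2/M was 0.705 in NPMc+, 0.71 in Flt3-ITD and 0.65 in NPMc+/Flt3-ITD over Mx and -0.088 over Flt3-ITD, with correlations of 0.219 and 0.267. Without the top 1% of cells of each gene G2/M was 0.82, 0.70 and 0.64 in NPMc+, Flt3-ITD and NPMc+/Flt3-ITD over Mx, with correlations of 0.257 and 0.262.

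In female cells G2/M was 0.25, 0.31 and 0.85 in the same order over Mx, and reversed in NPMc+/Flt3-ITD over Flt3-ITD (0.48) and over NPMc+ (0.565). Quiescence was -0.086 in NPMc+ and -0.049 in NPMc+/Flt3-ITD over Mx, and the correlations were 0.352 and 0.083. For NPMc+/Flt3-ITD over Mx it reversed megakaryocyte (0.49), erythroid (0.83), Hox (0.006), interferon (0.033) and adhesion genes (0.029). Over Flt3-ITD it reversed megakaryocyte (0.57), erythroid (0.95) and Hox genes (0.40). Over NPMc+ it reversed myeloid (-0.13), erythroid (0.34), interferon (0.22), heat shock (0.22) and adhesion genes (0.021). The p53 targets reversed in Flt3-ITD over Mx (-0.017), as did the log2 ratio of Ngp in Flt3-ITD over Mx (3.19). Mki67 was found in 2.93% of Mx, 4.40% of Flt3-ITD and 2.38% of NPMc+/Flt3-ITD cells.

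Without thinning, in the order Mx, NPMc+, Flt3-ITD and NPMc+/Flt3-ITD, at least 3 UMIs of the G2/M list were found in 97.1%, 99.0%, 98.0% and 99.3% of cells, Mki67 in 8.65%, 14.6%, 13.2% and 9.15% and Top2a in 21.1%, 26.3%, 25.7% and 24.8%. With at least 2 UMIs of the list the shares were 98.1%, 99.1%, 99.0% and 99.5%, and with at least 5 UMIs 74.7%, 79.7%, 83.6% and 91.6%. Clusters led by cell cycle genes held 3.22% of Mx and 2.77% of NPMc+/Flt3-ITD cells at resolution 0.3, 23.2% of Flt3-ITD and 14.1% of NPMc+/Flt3-ITD cells at resolution 1.0, and 2.82% of Mx and 0.60% of NPMc+/Flt3-ITD cells with cell cycle genes left out of the variable genes. With the stricter cell filter they held 15.6% of Mx, 9.19% of Flt3-ITD and 12.7% of NPMc+/Flt3-ITD cells. Clusters at least 90% from a single library held 88.5% of Flt3-ITD cells with the stricter filter and 95.6% of NPMc+/Flt3-ITD cells at resolution 0.3.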

Other observations

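The female cells of the double mutant library had other values than its male cells for some genes and not for others; the genes and the split were chosen after their values were seen. Among 2425 male and 179 female cells, Socs2 stood at 595.5 and 251.8 CPM, Cd48 at 763.5 and 325.7, Tcrg-C1 at 474.6 and 102 and Apoe at 128.9 and 896.1, while the ribosomal protein gene Rpl27 stood at 324.5 and 322.5 against 1916 and 1991 in Mx. Gm5611 was found in 94.97% of male and 95.5% of female cells of this library. The T-lineage cluster held 24.3% of the male and 1.12% of the female cells, and the erythroid-like cluster 10 of the 179 female cells. The megakaryocyte-like cluster held 5.59% of the female and 0.206% of the male cells, and the HSC-like cluster 3.35% and 0.247%. A cell cycle cluster held 6.145% and 0.289%, so the female cells were a small set spread otherwise over the clusters. The megakaryocyte-like and HSC-like clusters were drawn 96.0% and 98.1% from the NPMc+ library. Shares there can therefore mark likeness to that library and not a cell type. In Flt3-ITD, Cd48 stood at 275.2 CPM in male and 126.1 in female cells and Socs2 at 291.3 and 172, while in Mx the sexes were close for Cd48 (32.6 and 28.7) and Socs2 (33.5 and 35.7).

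Hprt, a purine salvage gene chosen after its values were seen, stood at 202.8 CPM in Mx, 260.7 in NPMc+, 228 in Flt3-ITD and 76.6 in NPMc+/Flt3-ITD, and in the last at 72.5 in male and 140.0 in female cells. Ribosomal protein and respiratory chain genes without shared sequence had a median log2 ratio over Mx of -0.30 in NPMc+/Flt3-ITD (26 of 58 at least 1.5-fold lower), and those with the largest shared portion -0.88 (21 of 39).

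The test in this paragraph was written down before its result was seen, but the 3 gene models had been picked by their levels and were already suspected to be copies of Npm1. UMIs of Gm5611, Gm14681 and Gm15484 in the NPMc+ and NPMc+/Flt3-ITD libraries could be transcripts of the NPMc+ transgene assigned to copies of Npm1: all 3 models matched Npm1, at a lowest identity of 92.2%. A match is needed by this explanation but does not set it apart from transcription of the copies themselves, and the reads were not analysed here, so the origin of these UMIs stays open.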
